A study of Mus musculus with 2 samples.

How the data were processed

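The measurement was RNA sequencing, labelled polyA mRNA, of whole lung of adult male mice of the B6NCrl strain, aged 8 weeks. There were 2 libraries in 1 group, replicate 1 and replicate 2, so no comparison between conditions was possible. The labels describe each as lung of an individual mouse and number them as biological replicates, but give both the same donor identifier. Whether they came from separate animals is therefore open, and differences between them measure only the spread between these samples.

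Per the file headers, the authors deposited for each gene an expected count, that is, an estimated count of reads that need not be whole because reads matching several transcripts are divided between them. The same deposited tables gave TPM, a transcript abundance scaled to a fixed total per library, and FPKM (fragments per kilobase, scaled to library size), and the transcript tables also gave each transcript's percent of its gene's TPM, per the file headers. The column layout was that of RSEM, but the aligner, the quantifier and their versions are not given in the sources used here. Per the lists deposited with the tables, the assembly was mm10 and the annotation M4. There was 1 table per library, and entries other than Ensembl genes were spike-ins and numbered entries, whose origin is not given in the sources used here. The effective length was 35 bases shorter than the length in 99.95% of entries. The deposited spread of each count due to shared reads was used to mark genes as uncertain when it exceeded 10% of the count. The library kit and whether strand was used are not given in the sources used here, so reads of overlapping or antisense genes cannot be assigned with certainty. The deposited credibility intervals of TPM were not used.

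Of the 69691 entries in each gene table, 43346 were Ensembl genes, 97 were spike-ins and 26248 carried only a number, with a median length of 73 bases. The numbered entries and spike-ins were kept out of library sizes and comparisons. The numbered entries held 0.0522% of all expected counts in replicate 1 and 0.0577% in replicate 2, and the spike-ins 0.0001% in each. Expected counts over Ensembl genes summed to 9049622 in replicate 1 and 8506606 in replicate 2. At this depth a count of 0, which allows up to 3 counts, corresponds to at most 3.32e-05% of the gene counts in replicate 1 and 3.53e-05% in replicate 2. Intervals and such limits cover counting error only, since reads without molecular identifiers are not independent molecules. Symbols, gene types and positions came from GENCODE M21 on GRCm38, the same assembly as mm10, matched on the gene identifier without its version. This matched 42462 of 43346 genes (97.96%). All positions are 1-based.

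Levels are given as TPM as deposited, as the mean ± SD of 2 libraries. A gene was called detected at a TPM of at least 1 in both. Ratios between libraries were taken on log2(TPM + 1), replicate 2 over replicate 1, a scale that understates differences of low genes. They were counted among genes with a mean expected count of at least 50. The counting error of each ratio of count shares came from an exact Clopper-Pearson 95% interval of the 2 rounded expected counts, with the totals of gene counts as offset. Such an interval compares these 2 libraries and not animals. Expected counts were rounded to whole numbers for edgeR 4.0.16 (R 4.3.3), which estimated the common biological coefficient of variation with TMM scaling, an intercept alone and filterByExpr. No differential test was run, because 2 samples of 1 group allow none. Correlations were across genes, which are not independent replicates, so they carry no p-value.

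Before the data were examined, 46 gene lists for cell types, tissues and pathways, 15 genes for isoform shares and the processing alternatives were fixed. Of the 474 symbols written out in the lists, Hbb-b1, Hbb-b2, Cyr61 and Muc16 had no match. The ribosomal protein list was built from a symbol pattern, which also took 10 S6 kinase genes. There were 11 genes in more than 1 list, among them Cbr2, Cyp2f2, Per1 and Klf2. For each list, the median log2 ratio over members with a mean TPM of at least 1 was placed among 10000 random lists of equal size, matched on mean expression in 20 bins. The percentile describes these libraries and is no test between animals, and random lists do not carry the co-expression that real lists have. At least 3 such members were required, which left out 4 lists.

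The genes named were fixed by a rule. It took the 20 genes of highest mean TPM and the 3 highest members of each list, or the highest 2 for skeletal muscle, cartilage, thymus and thyroid, liver, brain and adipocyte lists. It also took the 12 highest and 12 lowest log2 ratios among genes with a mean expected count of at least 200 whose counting interval excluded no change. The isoform genes, and list members under a TPM of 1 where the list median was above 10, completed it. Genes named outside the rule are said to have been chosen after their values were seen.

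Alternatives were other TPM minimums, FPKM, CPM scaled by TMM or by DESeq2 1.42.0 size factors, pseudocounts of 0.1 and 5, other count filters, TPM rescaled without mitochondrially encoded genes, and each library alone. After the data were seen, a rescaling of TPM was added, without 4 genes called ribosomal RNA-like here and without genes under 200 bases of effective length. The 4, Gm42418, ENSMUSG00000045999.9, Lars2 and Mir6236, were set by name. Whether their reads came from ribosomal RNA was not tested. Correlations over protein-coding genes alone and over genes of at least 200 bases, and a limit on shared reads, were also added then. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.

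The steps were tested on simulated counts drawn from the means of these libraries, and from their sizes except in the simulated lists. A simulated coefficient of variation of 0.1 was estimated as 0.0996 over 15826 genes. With counting error alone, the interval excluded no change for 98.0% of 200 genes changed by 2-fold and for 4.43% of unchanged genes, among 11837 genes. With the estimated spread between libraries added, it excluded no change for 26.9% of unchanged genes among 11793. Of 20 simulated lists of 12 genes shifted by 0.3 on the log2 scale, 14 lay outside the central 95% of random lists, against 0 of 20 unshifted lists, over 17478 genes. The simulated lists held genes drawn at random, which varied independently and with the same spread. They cannot show how often lists of co-expressed genes would fall outside.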

Results

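RNA of whole lung from adult male B6NCrl mice, an inbred black 6 strain, was sequenced in 2 libraries of 1 group, which the labels call polyA mRNA. Over Ensembl genes, replicate 1 held 9049622 expected counts and replicate 2 held 8506606. The series is a reference profile with no second condition, so levels come first and the spread between the 2 libraries follows. Values with an error are mean TPM ± SD, n = 2.

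Among protein-coding genes the highest levels were those of secretory products of the airway and alveolar epithelium. Scgb1a1, the secretoglobin of club cells (chromosome 19, 9083636 to 9087958, mm10), stood at 86404 ± 6579.5 TPM. Sftpc, surfactant protein C of alveolar type 2 cells (chromosome 14, 70520949 to 70524081), reached 22924 ± 2343 TPM. Apart from mitochondrially encoded genes and Lars2, the next protein-coding gene was the carbonyl reductase gene Cbr2 at 4899 ± 0.62 TPM. Lars2 is described with the genes called ribosomal RNA-like. A TPM of at least 1 in both libraries was reached by 16159 genes, of which 13038 were protein coding, out of 21474 protein-coding genes listed. A mean TPM of at least 10 was reached by 7173 protein-coding genes, at least 100 by 567 and at least 1000 by 36.

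Markers of the alveolar epithelium were high. All 12 alveolar type 2 genes were detected, with a median of 322 TPM, and Sftpb stood at 2449 ± 100.3 TPM and Sftpa1 at 2200.0 ± 0.71 TPM, both encoding surfactant proteins. All 12 alveolar type 1 genes were detected as well, with a median of 145 TPM. Ager, the receptor for advanced glycation end products, led them with 710.3 ± 44.4 TPM, ahead of Hopx with 565 ± 24.9 TPM and Emp2 with 214 ± 11.1 TPM. The 12 genes of surfactant lipid metabolism had a median of 50.7 TPM, led by the desaturase Scd1 with 399 ± 92.8 TPM, Elovl1 with 209 ± 9.91 TPM and the acyltransferase Lpcat1 with 180.3 ± 9.43 TPM.

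Among airway lists, club and ciliated cell genes were high and basal cell genes close to 0. The 10 club cell genes had a median of 522 TPM, with the cytochrome P450 gene Cyp2f2 at 1517 ± 85.3 TPM. The 12 ciliated cell genes had a median of 39.5 TPM, led by Sec14l3 with 655 ± 32.1 TPM, Tppp3 with 185 ± 12.2 TPM and Dynlrb2 with 66.2 ± 10.3 TPM. In contrast, 0 of 8 airway basal and squamous genes reached a TPM of 1 in both libraries, and the highest, the keratin gene Krt14, stood at 0.55 ± 0.41 TPM, with Sprr1a at 0.44 ± 0.14 TPM and Krt15 at 0.42 ± 0.17 TPM. Of 8 neuroendocrine genes, 5 were detected, all at low levels, with Syp at 3.33 ± 0.86 TPM, Calca at 2.45 ± 1.05 TPM and Uchl1 at 1.99 ± 0.78 TPM.

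Among vascular and stromal cells, all 16 endothelial genes were detected with a median of 96.8 TPM. Egfl7 stood at 430.2 ± 51.2 TPM, Ramp2, a subunit of the adrenomedullin receptor, at 253 ± 26.1 TPM and Plvap at 159 ± 1.00 TPM. The lymphatic endothelial list had a lower median of 9.05 TPM, with 6 of 7 genes detected. Its highest member Pdpn, at 97.9 ± 21.7 TPM, is also an alveolar type 1 marker, and was followed by Ccl21a at 45.2 ± 1.77 TPM and Lyve1 at 31.3 ± 2.08 TPM. The 12 fibroblast genes had a median of 75.1 TPM, led by the methyltransferase Inmt with 1326 ± 106 TPM, the actin-severing protein gene Gsn with 687 ± 52.5 TPM and Mfap4 with 162 ± 6.38 TPM. The smooth muscle and pericyte list had a median of 13.6 TPM, with Cox4i2 at 37.4 ± 5.68 TPM, Higd1b at 30.7 ± 6.30 TPM and Tagln at 25.2 ± 2.53 TPM. Of the mesothelial list, 6 members were measured, with a median of 49.97 TPM. Krt19, which epithelial cells also express, stood at 96.1 ± 4.41 TPM, the uroplakin gene Upk3b at 81.8 ± 41.6 TPM and mesothelin, Msln, at 69.0 ± 29.5 TPM.

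Immune lists had lower medians than the alveolar, club and ciliated cell lists. Alveolar macrophage genes had a median of 14.2 TPM, led by Chil3 with 182 ± 26.7 TPM, Ear2 with 54.2 ± 8.44 TPM and Plet1 with 42.2 ± 4.21 TPM. Monocyte and interstitial macrophage genes had a median of 8.82 TPM, with the complement gene C1qa at 24.2 ± 1.31 TPM, the receptor gene Csf1r at 20.3 ± 1.34 TPM and Ly6c2 at 19.3 ± 1.57 TPM. The B cell median was 8.20 TPM, with the immunoglobulin heavy chain genes Ighm at 22.6 ± 2.77 TPM and Ighd at 14.8 ± 0.53 TPM, and Cd22 at 9.88 ± 2.83 TPM. The plasma cell median was 7.30 TPM (5.02 in replicate 1 alone and 9.57 in replicate 2 alone). Its highest members were Sdc1 at 71.2 ± 3.02 TPM, Xbp1 at 71.0 ± 1.11 TPM and the light chain gene Igkc at 41.9 ± 1.8 TPM. Which cells expressed Sdc1 and Xbp1 was not tested. For T and NK cells the median was 1.98 TPM, with 10 of 12 genes detected, among them the granzyme gene Gzma at 11.6 ± 1.11 TPM, Trbc2 at 6.99 ± 0.70 TPM and Cd3g at 5.37 ± 0.45 TPM. Of 12 neutrophil genes 7 were detected, with a median of 3.23 TPM (1.54 in replicate 1 alone and 4.52 in replicate 2 alone) and S100a9 at 57.8 ± 28.0 TPM, S100a8 at 43.3 ± 17.7 TPM and Csf3r at 6.18 ± 0.28 TPM. Of 7 mast cell and basophil genes 0 were detected in both libraries, and Cpa3, the highest, stood at 0.62 ± 0.59 TPM, with Cma1 and Tpsb2 each at 0.19 ± 0.08 TPM. The 9 genes of MHC class II presentation were all detected with a median of 22.1 TPM, led by Cd74 with 340.5 ± 3.96 TPM, H2-Aa with 195 ± 14.6 TPM and H2-Ab1 with 151 ± 13.4 TPM.

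Markers of blood and of other tissues were measured at a range of levels. Of 7 platelet genes 5 were detected, with a median of 2.72 TPM, Ppbp at 18.1 ± 10.6 TPM, Pf4 at 12.9 ± 4.30 TPM and Itga2b at 6.17 ± 0.11 TPM. The erythroid list was led by the globin genes Hbb-bs at 3164 ± 813 TPM, Hba-a2 at 2950 ± 587 TPM and Hba-a1 at 1162 ± 165 TPM, whereas the red cell membrane genes Slc4a1 and Gypa stood at 0.97 ± 0.42 and 0.27 ± 0.17 TPM. Of 13 cardiac muscle genes 12 were detected, with a median of 11.5 TPM and the atrial light chain gene Myl7 at 49.4 ± 31.2 TPM, Tnni3 at 34.3 ± 10.03 TPM and Tnnt2 at 30.8 ± 14.7 TPM. Myosin-binding protein C, Mybpc3, was under a TPM of 1, at 0.94 ± 0.50. Skeletal muscle genes had a median of 0.39 TPM, with Mylpf at 10.4 ± 1.48 TPM and Tnni2 at 1.93 ± 0.11 TPM. Adipocyte genes had a median of 2.49 TPM (3.58 and 1.39 in each library alone), with Cfd at 14.2 ± 12.1 TPM and Cidec at 8.96 ± 5.37 TPM. Cartilage genes had a median of 0.05 TPM, although Chad alone reached 25.9 ± 0.19 TPM and the next, Hapln1, 0.10 ± 0.02 TPM. Thymus and thyroid, liver and brain lists had medians of 0.11, 0.62 and 0.56 TPM, against 0.10, 0.77 and 0.83 in replicate 1 alone and 0.20, 0.36 and 0.27 in replicate 2 alone. Their highest members were Iyd at 3.80 ± 1.25 and Themis at 0.48 ± 0.14 TPM, Alb at 3.07 ± 2.09 and Tat at 1.97 ± 0.76 TPM, and Stmn2 at 22.5 ± 2.96 and Mbp at 12.1 ± 1.23 TPM.

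**Figure D1:**
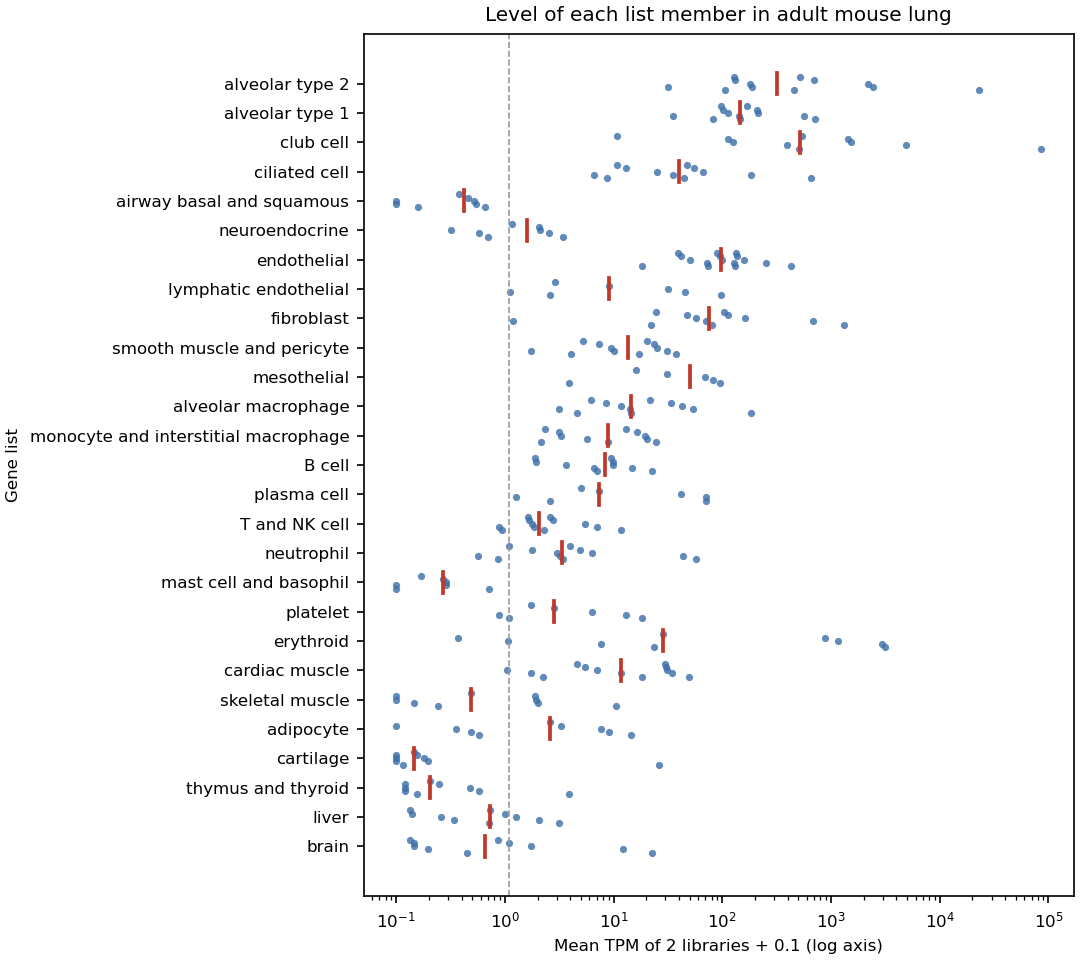
Each point is 1 gene of a fixed cell type or tissue list, placed by its mean TPM over the 2 lung libraries plus 0.1 on a log axis, and each red bar is the list median. The dashed line marks a TPM of 1, and medians run from 0.05 TPM for cartilage to 522 TPM for club cells.

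Lung transcription factors were all detected, and genes of xenobiotic metabolism were high. The 16 transcription factor genes had a median of 26.6 TPM. Epas1, which encodes the hypoxia-inducible factor HIF-2 alpha, stood at 371 ± 50.6 TPM, Klf2 at 86.6 ± 14.0 TPM and the lung lineage factor Nkx2-1 at 78.2 ± 4.64 TPM. The 16 genes of xenobiotic metabolism had a median of 203 TPM, and after Cbr2 and Cyp2f2, which also belong to the club cell list, came the aldehyde dehydrogenase gene Aldh1a1 with 507 ± 15.1 TPM. The 16 extracellular matrix genes had a median of 57.8 TPM, led by the matrix Gla protein gene Mgp with 1748 ± 143 TPM, Sparc with 943 ± 62.8 TPM and Bgn with 385 ± 11.7 TPM. Of the 10 genes for the renin-angiotensin system and coronavirus entry 7 were detected, with a median of 6.26 TPM, led by the angiotensin-converting enzyme gene Ace with 144 ± 14.8 TPM, Ctsl with 62.8 ± 2.44 TPM and Furin with 34.5 ± 1.00 TPM.

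Stress, signalling, rhythm and proliferation lists had medians from 3.03 to 45.5 TPM. Immediate early genes had a median of 18.4 TPM with Ier3 at 109 ± 1.70 TPM, and the glucocorticoid and metal list had a median of 45.5 TPM (30.03 and 50.33 in each library alone) with the metallothionein gene Mt1 at 163 ± 48.9 TPM and Tsc22d3 at 101 ± 6.84 TPM. Heat shock genes had a median of 25.2 TPM, led by the chaperone genes Hspa8 with 371 ± 24.1 TPM, Hsp90aa1 with 199 ± 63.7 TPM and Hspb1 with 83.2 ± 12.6 TPM. In the hypoxia list, with a median of 13.6 TPM, the growth factor gene Vegfa stood far above the rest at 530.1 ± 28.6 TPM, followed by Ldha at 154 ± 4.33 TPM and Bnip3 at 33.5 ± 1.54 TPM, while the prolyl hydroxylase gene Egln3 stood at 0.70 ± 0.23 TPM. Circadian clock genes had a median of 22.6 TPM, with the output factors Tef at 261 ± 28.4 TPM and Dbp at 94.0 ± 22.6 TPM and the period gene Per1 at 88.2 ± 3.09 TPM. Interferon response genes were all 14 detected with a median of 8.92 TPM, led by Bst2 with 48.0 ± 0.35 TPM, Oasl2 with 35.1 ± 4.67 TPM and Ifit3 with 34.7 ± 0.08 TPM. Proliferation genes were low, with a median of 3.03 TPM and Cenpa at 5.79 ± 1.13 TPM, Cdk1 at 4.96 ± 0.08 TPM and Ccnb1 at 4.13 ± 3.58 TPM.

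Housekeeping genes had a median of 181 TPM, with Eef1a1 at 2110.3 ± 95.2 TPM, Actb at 1762 ± 44.4 TPM and B2m at 697 ± 7.07 TPM. The ribosomal protein list had a median of 282 TPM over 95 genes, led by Rps27rt with 1933 ± 376 TPM, Rpl41 with 1081 ± 74.3 TPM and Rps15 with 979 ± 40.8 TPM. Below a TPM of 1 in it were the S6 kinase genes Rps6ka6 at 0.88 ± 0.57 and Rps6kl1 at 0.79 ± 0.30, and the ribosomal protein paralogs Rpl3l at 0.54 ± 0.17, Rpl39l at 0.26 ± 0.36 and Rpl10l at 0.14 ± 0.20. The Y-linked genes Eif2s3y, Ddx3y and Kdm5d stood at 30.7 ± 1.73, 15.7 ± 0.78 and 9.59 ± 0.25 TPM, against 0.62 ± 0.11 TPM for Xist, the RNA of the inactive X chromosome, and the labels give male mice. The list median was 9.59 TPM.

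The 20 highest genes took 47.0% ± 0.38 (SD, n = 2) of all TPM, and most of them were not messenger RNAs of the nuclear genome. An identifier without a name in the annotation used here, ENSMUSG00000045999.9, led with 114387 ± 964 TPM, and Gm42418, a long noncoding RNA (chromosome 17, 39846958 to 39848788) annotated where 45S ribosomal RNA sequence lies, stood at 77514 ± 888 TPM. Together they held 23.9% of all expected counts in replicate 1 (exact 95% interval 23.89 to 23.95%) and 23.8% in replicate 2 (23.80 to 23.85%). Mir6236 followed with 46358 ± 4336 TPM and Lars2 (chromosome 9, 123366927 to 123462666) with 6999 ± 1103 TPM. The small RNAs mt-Ts1, Snord14d and Snord14c, at 19658 ± 5108, 17048 ± 1456 and 10514.5 ± 50.1 TPM, Rn7sk at 6500.5 ± 1045 TPM, Rny3 at 4147 ± 425 TPM and the unnamed ENSMUSG00000089855.1 at 10268 ± 2228 TPM were also among the 20. Genes of effective length under 200 bases held 1.02% of the expected counts in replicate 1 and 17.6% of its TPM. In replicate 2 they held 1.08% and 18.0%. Levels depend on these genes. The rescaling without short genes and the 4 genes called ribosomal RNA-like was added after the data were seen. It multiplies the TPM of each remaining gene by 1.64 in replicate 1 and 1.66 in replicate 2. Whether reads of the 4 genes came from ribosomal RNA was not tested.

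Mitochondrially encoded genes were all 13 detected, with a median of 2153 TPM, led by the cytochrome oxidase subunits mt-Co1 at 7137 ± 246 TPM, mt-Co2 at 6539.5 ± 228 TPM and mt-Co3 at 5214 ± 388 TPM. The ribosomal RNAs mt-Rnr1 and mt-Rnr2 stood at 7084 ± 540.1 and 4310.0 ± 253 TPM. Gm10925, annotated as a pseudogene on chromosome 1 (24613974 to 24614651), stood at 4765 ± 42.8 TPM. Shared-read spreads were 3.0% of the count for Gm10925 and 6.94% for mt-Co3. Whether the reads of Gm10925 came from that locus was not tested, and they are left out of the mitochondrial share. The whole mitochondrial chromosome held 4.20% of expected counts in replicate 1 (4.19 to 4.21%) and 4.13% in replicate 2 (4.11 to 4.14%). Of the 13 genes in the list of RNA without a poly(A) tail 10 were detected, with a median of 336 TPM, and Rn7sk held 16208.65 expected counts in replicate 1 and 12247.39 in replicate 2, so RNA of this kind was read in libraries labelled polyA. Besides Rn7sk and Rny3 it was led by Rn7s2 at 3758 ± 1349 TPM, whose count is uncertain because its spread from shared reads was 36.1%. In the same list Terc stood at 0.17 ± 0.24 TPM, and the histone gene Hist1h3b had 0 counts in both libraries, which allows up to 3.32e-05% of the gene counts in replicate 1. The nuclear long noncoding RNAs had a median of 18.8 TPM, with Malat1 at 7741 ± 63.0 TPM, Neat1 at 1274 ± 32.4 TPM and Gas5 at 142 ± 5.37 TPM.

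The 2 libraries gave closely similar levels for most genes. Across 17478 genes with a mean TPM of at least 1, Pearson's r of log2(TPM + 1) was 0.953 and Spearman's rho 0.954. Over the 13407 protein-coding genes, a subset chosen after the data were seen, r was 0.983. The common biological coefficient of variation estimated by edgeR was 8.95% over 15774 genes. Their counts differed by more than sampling noise, with a chi-square of 71139 on 15773 degrees of freedom, 4.51 times that number, as separately made libraries would, which does not show that they came from separate animals.

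Of 11827 genes with a mean expected count of at least 50, 66 differed by 2-fold or more on the log2(TPM + 1) scale, 28 higher and 38 lower in replicate 2, and 65 of these had a counting interval that excluded no change. Restricting the count, in a step added after the data were seen, to genes with a shared-read spread of at most 10% left 48, of which 15 were higher and 33 lower. At any size, the counting interval of 2106 genes, 17.8%, excluded no change. In simulated counts with the estimated spread between libraries it did so for 26.9% of unchanged genes. That simulation gave every gene the same spread, estimated from these same libraries, so its share cannot show how many of the 2106 genes differ. The median log2 ratio was −0.01 and its SD 0.27.

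Among genes lower in replicate 2, Bpifa1, a secreted protein of the airway surface (chromosome 2, 154142880 to 154149219), stood at 195 TPM in replicate 1 and 28.8 TPM in replicate 2, a ratio of count shares of 0.154 (95% interval 0.132 to 0.178). Its neighbour Bpifb1 had a ratio of 0.229 (0.184 to 0.281) and the secretoglobin gene Scgb3a1 (chromosome 11, 49663610 to 49665118) one of 0.316 (0.290 to 0.346). The atrial myosin gene Myl7 had a ratio of 0.387 (0.308 to 0.483), and Lrrn4, of the mesothelial list, and Aldh1a2, a retinoic acid synthesis gene, had ratios of 0.415 (0.356 to 0.481) and 0.427 (0.361 to 0.504). The predicted genes Gm10800 and Gm10801, on chromosome 2 between 98662237 and 98667301, had ratios of 0.277 (0.260 to 0.294) and 0.280 (0.243 to 0.322), and Gm26870 on chromosome 9 one of 0.284 (0.235 to 0.340). Gm10335, with 0.089 (0.061 to 0.125), and Rps6-ps4, with 0.319 (0.257 to 0.391), are uncertain because their shared-read spreads were 23.9% and 17.4% of the count.

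Genes higher in replicate 2 included the metallothionein gene Mt2 (chromosome 8, 94172664 to 94173568), at 29.5 TPM in replicate 1 and 128 TPM in replicate 2, a ratio of 4.39 (95% interval 3.58 to 5.43). Spp1, osteopontin, had a ratio of 2.16 (1.89 to 2.47), the retinoic acid hydroxylase gene Cyp26b1 one of 2.32 (1.88 to 2.86), S100a9, a calcium-binding protein of neutrophils, one of 2.07 (1.67 to 2.56) and the collagen cross-linking enzyme gene Lox one of 2.02 (1.78 to 2.30). The early-response genes Dusp1 and Egr1 had ratios of 1.88 (1.70 to 2.08) and 2.08 (1.69 to 2.57), and Gm12346 one of 2.02 (1.75 to 2.31). Rpl10-ps3, Rps3a2 and Gvin1, with ratios of 4.19, 2.30 and 2.498, are uncertain, with shared-read spreads of 18.1%, 12.3% and 32.5%. Gm28661, with a ratio of 12.9 and a spread of 36.4%, lies next to Gm29216, with a ratio of 0.266 (0.242 to 0.292), on chromosome 1 between 24614885 and 24616197, so these are reported as uncertain.

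**Figure D2:**
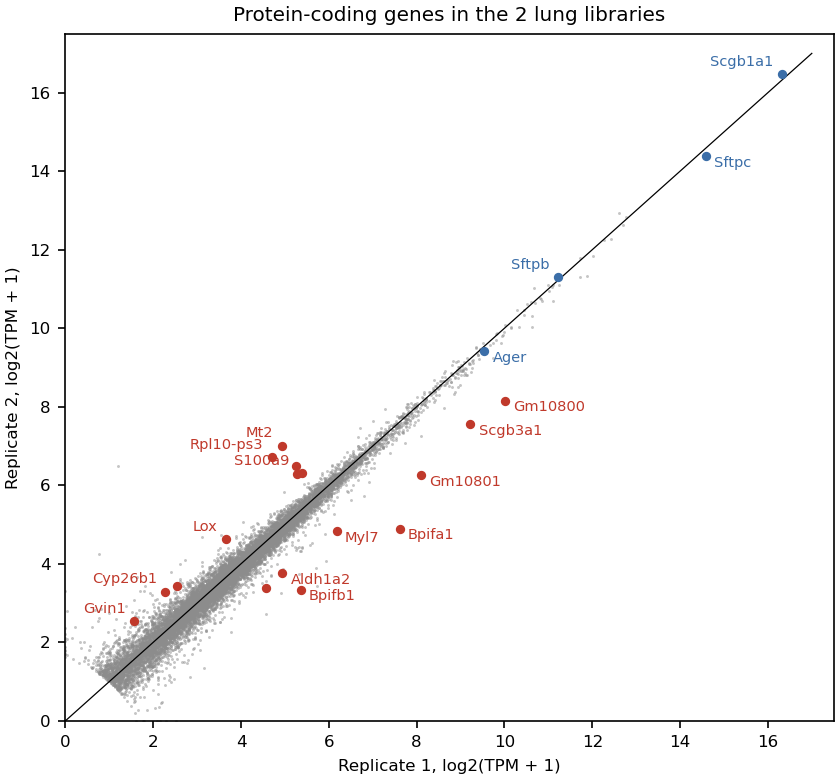
Each grey point is 1 protein-coding gene with a mean TPM of at least 1, placed by log2(TPM + 1) in replicate 1 (horizontal) and replicate 2 (vertical), and the line marks equal levels. Red points are the protein-coding genes of the rule for the highest and lowest ratios, such as Mt2 at 29.5 and 128 TPM, labelled where space allows, and blue points are the 4 epithelial genes Scgb1a1, Sftpc, Sftpb and Ager.

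By gene list, 16 of 42 lists lay outside the central 95% of matched random lists, 9 higher and 7 lower in replicate 2. For lists of genes that vary independently 2.1 would fall outside. Members of real lists vary together, so 2.1 is no chance expectation for them. The lists lower in replicate 2 with the lowest medians of log2 ratio were liver, −1.08 over only 3 genes, adipocyte, −1.004 with 5 of 5 genes lower, mesothelial, −0.79 with 6 of 6 lower, and cardiac muscle, −0.66 with 12 of 12 lower. Smaller differences were seen for erythroid genes, −0.31 with 7 of 7 lower, alveolar macrophage genes, −0.23 with 9 of 12 lower, and alveolar type 1 genes, −0.16 with 11 of 12 lower. The erythroid count leaves out Slc4a1 and Gypa, which lay under a mean TPM of 1. Both were higher in replicate 2, with log2 ratios of 0.44 on 10 and 24 counts and 0.27 on 2 and 5 counts. The liver list rests on Alb, Tat and Ahsg at low levels, and Alb had 69 counts in replicate 1 and 23 in replicate 2.

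Higher in replicate 2 were the neutrophil list, with a median of 0.84 and 7 of 9 genes higher, and the immediate early list, with 0.55 and 15 of 16 higher. The glucocorticoid and metal list had a median of 0.44 with 10 of 12 higher, proliferation genes 0.44 with 9 of 11 higher, heat shock genes 0.35 with 8 of 10 higher and B cell genes 0.32 with 9 of 10 higher. Smooth muscle and pericyte genes, at 0.24 with 11 of 12 higher, endothelial genes, at 0.15 with 15 of 16 higher, and lung transcription factors, at 0.12 with 13 of 16 higher, differed by less. The alveolar type 2, club cell, ciliated cell and fibroblast lists, with medians of −0.04, 0.03, −0.09 and −0.05, lay within the range of random lists. The median and the mean differed in sign for 8 lists, 0 of which lay outside the range. In the club cell list the mean was −0.45, set by Bpifa1, Scgb3a1 and Muc5b. Muc5b and Ahsg were named after their values were seen.

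**Figure D3:**
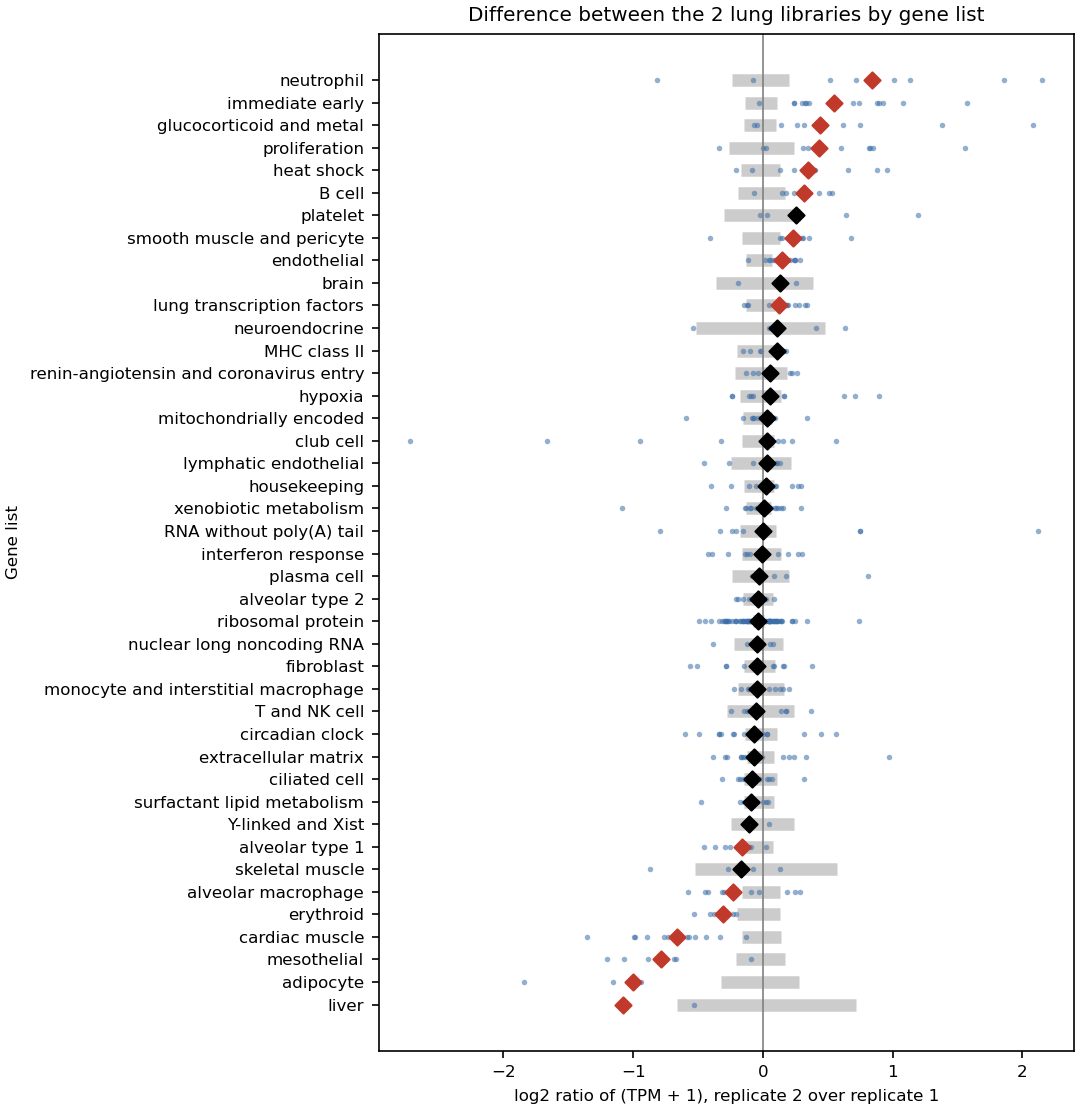
Each diamond is the median log2 ratio of (TPM + 1), replicate 2 over replicate 1, of 1 gene list, small points are its members with a mean TPM of at least 1, and grey bars span the central 95% of 10000 random lists matched on expression. The 16 red diamonds lie outside their bars, from −1.08 for liver to 0.84 for neutrophil genes.

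Isoform shares were estimated for 15 genes, and 11 of these had more than 1 transcript. Of the 11, the same isoform ranked first in both libraries for 8. Sftpa1-201 made up 72.7% ± 0.63 of Sftpa1 TPM (SD, n = 2), Pkm-201 70.2% ± 8.62 of the pyruvate kinase gene Pkm, and Ndrg1-201 58.4% ± 0.10 of Ndrg1. The receptor gene Ager was divided between Ager-201 at 42.9% ± 1.86 and Ager-209 at 34.1% ± 3.49, with the retained-intron transcript Ager-204 at 17.2% ± 1.85. For Sftpb the first isoform, Sftpb-204, held 34.1% ± 2.63, and Sftpb-201 had 0 counts in replicate 1 and 1289.6 in replicate 2, so the division between its isoforms is uncertain. Vegfa-207 held 27.1% ± 1.02 of Vegfa, Cav1-201 26.5% ± 1.09 of the caveolin gene Cav1 and Tpm1-219 21.9% ± 2.42 of the tropomyosin gene Tpm1. Tpm1-219 is annotated as a processed transcript of 649 bases. It held 224 and 144 counts in replicates 1 and 2, fewer than the protein-coding Tpm1-215 with 357 and 218. In Cd44, Fgfr2 and Fn1 different isoforms ranked first in the 2 libraries, and the leading isoform by mean share held 23.7% ± 2.07, 17.9% ± 1.36 and 16.3% ± 1.77. For Fn1 this was Fn1-205, annotated as a nonsense-mediated decay transcript of 426 bases, which ranked first in neither library. It held 28.2 and 34.7 counts in replicates 1 and 2, against 594 and 587 for the protein-coding Fn1-216. Scgb1a1, Sftpc, Eln and Myl6 had a single transcript in the annotation of the files.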

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

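Signals outside the gene measurements were set against the 3 counts that a count of 0 allows. The labels name a spike-in set, and the 97 spike-in sequences together received 7.0 expected counts in replicate 1 and 7.0 in replicate 2, on 4 sequences. ERCC-00054 held 5 counts in each library, and the other 3 held at most 1 each. With so few counts the spike-ins gave no usable scale for either library.

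The 26248 numbered entries, which have a median length of 73 bases, received 4726.37 expected counts in replicate 1 and 4910.93 in replicate 2. These were 0.0522% (exact 95% interval 0.0507 to 0.0537%) and 0.0577% (0.0561 to 0.0593%) of all expected counts. On the TPM scale the same entries held 1.61% and 1.76%, because TPM divides by very short effective lengths. The most read entry held 414 counts in replicate 1.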

How the results depend on the processing

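No gene list outside the random range reversed. The 16 called gene lists kept their side of the random lists under each alternative that gave a value, except that the liver list had too few genes under FPKM to be placed. Their order was not fixed, since under TMM the adipocyte list, at −1.201, lay below the liver list, at −1.17. Other lists moved outside under single settings: platelet genes, higher in replicate 2, under TMM and with a pseudocount of 0.1, extracellular matrix genes and RNA without a poly(A) tail under TMM, and circadian clock genes under FPKM. The coefficient of variation was 8.95% with DESeq2 size factors and 9.60% without the filter. With a TPM minimum of 5, 10537 genes were detected, by construction fewer. The share of the 20 highest genes was 38.8% of expected counts, 48.8% of TPM without mitochondrially encoded genes and 31.6% after the rescaling added later, since each changes what the shares sum over. Pearson's r was 0.877 with a pseudocount of 0.1, 0.979 with 5, 0.979 without the filter and 0.985 on CPM, and, in the alternatives added later, 0.983 over protein-coding genes and 0.977 over genes of at least 200 bases; the cause was not tested. The number of genes differing by 2-fold was 97 with a pseudocount of 0.1 (38 higher and 59 lower in replicate 2), 37 with one of 5 (17 and 20), 1414 with no filter (710 and 704), which adds genes of few counts, and 27 with a mean count of at least 200 (7 and 20). By TMM it was 66 (33 and 33) and by DESeq2 63 (28 and 35), so more genes were lower than higher in each setting except with no filter and under TMM. No paired analysis was possible because there is 1 group. Other splits of the samples were not possible with 2 libraries. The median trended coefficient of variation was 13.1% in the lowest quartile of expression and 8.30% in the highest; the cause was not tested. As to depth, a count of 0 allows up to 3 counts per library.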

Other observations

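Of the tests given here, the globin test was chosen only after the result was seen, as were the genes named outside the rule. The intervals of the medians of second gene sets, which span at least 95% over genes, were also added then.

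Several abundant protein-coding genes lay outside the fixed lists. The lysozyme gene Lyz2 stood at 3909 ± 358 TPM (SD, n = 2), the thymosin gene Tmsb4x at 2312 ± 154 TPM, Tpt1 at 1624 ± 48.4 TPM and the ferritin genes Fth1 and Ftl1 at 1398 ± 14.4 and 1340 ± 61.2 TPM. Within the club cell list, members went both ways between the libraries. Scgb1a1 had a log2 ratio of 0.16 in replicate 2 over replicate 1 and Retnla one of 0.56, whereas Scgb3a2 had −0.32, Muc5b −0.94, Scgb3a1 −1.67 and Bpifa1 −2.72. Coronavirus entry and angiotensin genes included Tmprss2 at 24.98 ± 0.47 TPM and Ace2 at 6.59 ± 0.82 TPM, and Ren1 had 0 counts in both libraries.

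The mesothelial, cardiac muscle and adipocyte lists were lower in replicate 2, with medians of −0.79, −0.66 and −1.004. Sets of other genes were chosen before their values were seen. For heart muscle the median was −0.63 (−1.03 to −0.461), with 15 of 17 genes lower, among them Mb, Tcap and Csrp3. This is the value that less cardiac muscle in the tissue of replicate 2 predicts. Where in the tissue that muscle lay was not tested. For mesothelium the median was −0.62 (−0.78 to −0.0861) with 13 of 16 lower, the value that less pleural lining predicts, but the interval includes the bound of −0.1 written against it and genes such as C3, at 319.5 TPM, are also expressed by other lung cells, so the support is weaker. A second fat set had a median of 0.0172 (−0.66 to 0.20) with 5 of 10 genes lower, so a difference of the size in the fixed list was not seen over these genes, whose members went both ways, from Thrsp at −1.27 to Adrb3 at 0.22, with Pparg at −0.05. By the rule written beforehand this median counts against less fat, since it lies above −0.1. Its interval, added after the result was seen, includes that bound, so less fat cannot be told apart from other reasons. In the second fat set, Cdo1, Pnpla2 and Lpl had mean levels of 71.7, 63.8 and 43.5 TPM. The highest gene of the fixed list, Cfd, stood at 14.2 TPM. Other lung cells may express such genes, which was not tested, so the second set may miss a loss of fat. With 1 group, the design cannot test why the libraries differ.

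The neutrophil list was higher in replicate 2, with a median of 0.84 and 7 of 9 genes higher, but Ltf had a log2 ratio of −0.81. Csf3r had one of −0.08 on TPM, but a ratio of count shares of 1.17 (95% interval 0.84 to 1.64), so its direction is not settled. Summed reads of 4 globin genes had a ratio of 0.748 in replicate 2 over replicate 1 (95% interval 0.737 to 0.759), below what more whole blood left in the tissue predicts. Globin genes lead the erythroid list, already seen to be lower when this test was chosen, so the ratio is no independent test. White cells or platelets without red cells are not covered by the globin ratio. The platelet genes Ppbp and Pf4 had ratios of 2.43 (1.87 to 3.18) and 1.63 (1.09 to 2.48) and the red cell gene Slc4a1 one of 2.55 (1.18 to 5.98). A second set of neutrophil genes had a median of 0.0591 (−0.26 to 0.16) with 7 of 12 higher, Cd177 at −0.26 and Itgam at 0.13. By the rule written beforehand this median counts against more neutrophil RNA, but its interval, added after the result was seen, includes the bound. Other lung cells may also express genes of this set, such as Hdc at 37.8 TPM and Lrg1 at 22.0 TPM, which was not tested. More neutrophil RNA therefore cannot be told apart from a difference in a few genes such as Ngp, with 5 and 49 counts, and Camp, with 3 and 21. The design cannot test why the libraries differ.

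The immediate early list was higher in replicate 2, with a median of 0.55 and 15 of 16 genes higher, led by Fos at 7.58 and 24.6 TPM and Fosb at 0.82 and 2.85 TPM. Reads shared between gene copies were argued against, since the median spread of the count from shared reads was 0.0% of the count. Transcript length and GC content were argued against too, since the list lay at percentile 100 among random lists matched on either. A second early-response set had a median of 0.25 (0.0224 to 0.39) with 16 of 19 genes higher, such as Nr4a2 and Ppp1r15a, the value that a wider early-response program in replicate 2 predicts, but the interval includes the bound of 0.05 written against it, so the support is weak. Why the libraries differ in it, for example in handling of the tissue or in the animals, stays open, and the design cannot test it.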
